A study of Arabidopsis thaliana with 4 samples.

How the data were processed

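Gene expression was measured in whole Arabidopsis seedlings on 4 two-colour Agilent arrays of one slide. Per the labels, RNA of ORA47-GR seedlings given CYC and DEX carried Cy5 on every array, and Cy3 marked either WT given CYC and DEX or ORA47-GR given CYC, with 2 replicates of each and no dye swap. Groups and replicate numbers come from the sample titles.

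The scanner files hold spot intensities, as mean signals and local backgrounds of both dyes, as deposited by Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. They also hold the log10 ratio of processed Cy5 over Cy3 signal, background-corrected and dye-normalized, per the file headers. The deposited value table holds log2 ratios. Set against the scanner files it equalled that log10 ratio turned to log2, within 0.005, with the direction Cy5 over Cy3 and array medians of 0.02, 0, 0 and 0, so scale, centring and direction were all settled. Other deposited columns used are flags, with no unit, set by the authors' software for spots well above background, saturated or outlying. No spot was saturated, and between 84 and 132 spots an array were left out as outliers.

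Mean intensities were background-corrected with normexp (offset 50), and ratios were normalized within each array by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots of one probe were averaged. A gene was represented by its probe of highest mean signal; 7743 of the tested genes have several. Probes were named from the locus tag in the files or from an accession, symbol or synonym in a RefSeq table of assembly TAIR10.1. Of 43603 probes 37217 (85.4%) matched a locus and 6386 did not. The coordinates printed are those of the array files, whose header names another build, and none come from the table. Of 26830 genes with complete data, 24454 were tested, those well above background in at least one channel on both arrays of at least one comparison.

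One limma fit of all 4 arrays gave each comparison a coefficient, with 2 residual degrees of freedom, and their difference as a contrast. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. P-values of single genes, and those of fry below, are two-sided and measure the spread between these arrays only. Errors of log2 ratios are standard errors of this fit. Gene lists (24, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera sets the genes of a list against all other genes. Its two-sided p-values therefore rest on the spread across genes and do not measure the spread between arrays alone. No list kept its call with an estimated correlation, which rests on 2 residual degrees of freedom. By fry, which asks whether a list's genes move one way on balance, 4 lists passed over WT, which were core jasmonate signalling, salicylic acid defence, reference genes and circadian clock (adjusted p = 0.031 each), and detoxification passed over uninduced (adjusted p = 0.047).

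The genes named were fixed by rule. ORA47 was always named. For each comparison these were the 12 largest rises and 8 largest falls among called genes of one sign on both arrays and well above background in Cy5 or Cy3. For both comparisons together they were the 10 largest each way by the smaller ratio, and for their difference the 5 largest each way. For each list they were up to 4 called members, or 2 uncalled ones given as values. All could be measured on both sides, so no bound was needed. One root marker that the rule names is not reported here.

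The steps were tested on simulated data. In simulated over-WT ratios for 24454 genes, all 50 genes changed 3-fold and 66% of those changed 2-fold were called, with 6 false calls. In simulated over-uninduced ratios, all 50 changed 3-fold and 64% changed 2-fold were called, with 2 false calls. The simulated noise took each gene's spread from the fit, so recovery in the real arrays may be lower. There TAT3, at a log2 ratio of -1.72 over WT, was not called (limma adjusted p = 0.068). Of 200 random unchanged lists, 4% over WT and 2% over uninduced had an unadjusted camera p under 0.05. The simulated genes varied independently of each other, so these shares do not hold for lists whose genes vary together. Estimated correlations of the real lists ranged from -0.10 (core jasmonate signalling) to 0.91 (JAZ repressors).

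The replicate numbers were checked for pairing. Differences between replicates 1 and 2 of the comparisons correlated with r = -0.12 across genes for the log2 ratios and -0.66 for the Cy5 levels, so equal numbers do not deviate together. Cy5 channels with unequal numbers in the 2 comparisons lay closer (root mean square log2 differences of 0.207 and 0.251) than those with equal numbers (0.348 and 0.292). The labels do not say whether Cy5 RNA was shared between arrays, so the comparisons are not known to be independent. Alternatives covered background correction, normalization, the value table, the filter, the probe rule, the model, the thresholds and each replicate. A promoter motif search was not run, since no genome sequence was used here. Scan and slide could not be tested as batches because all arrays share them.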

Results

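ORA47 is an AP2/ERF transcription factor of Arabidopsis thaliana. The seedlings were 7 days old and of the Columbia ecotype. One line carried 35S:ORA47-GR, in which a constitutive promoter drives ORA47 fused to the glucocorticoid receptor, so that dexamethasone (DEX) lets the fusion protein into the nucleus. Cycloheximide (CYC), which blocks protein synthesis, was given at 50 µM for 1 h, and DEX at 20 µM followed for 2 h. RNA from ORA47-GR seedlings given CYC and DEX was labelled with Cy5 on all 4 two-colour arrays. On 2 arrays the Cy3 channel held wild type (WT) given CYC and DEX, and on the other 2 it held ORA47-GR given CYC without DEX. The ratios are called "over WT" and "over uninduced" below, with n = 2 arrays each. The labels call them biological replicates. The stated purpose was to take genes raised in both as putative direct targets, with the effects of either chemical and of the transgenic background excluded.

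All 4 arrays gave signal well above background. The median gene spot had a Cy5 signal between 1169 and 1579 and a Cy3 signal between 523.2 and 664.1, against medians of 59.9 to 61.5 and 40.5 to 41.1 for the negative-control spots. Between 86.6% and 88.9% of gene spots were well above background in Cy5 and between 85.6% and 87.4% in Cy3. Log2 ratios of the replicates correlated across genes with r = 0.87 over WT and r = 0.74 over uninduced. Genes are not independent replicates, and the number of arrays limits the precision. Every array had the same dye orientation, so a gene-specific dye effect is part of each ratio.

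The ORA47 transcript was measured first, since the construct places ORA47 behind a constitutive promoter. Its only probe (A_84_P19028) lies on chromosome 1 from 28148418 to 28148477 by the array file, with the sequence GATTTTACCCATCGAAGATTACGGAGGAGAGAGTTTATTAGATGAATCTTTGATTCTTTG. ORA47 (AT1G74930) stood 1.58-fold over WT, a log2 ratio of 0.66 ± 0.07 (SE of the limma fit, n = 2; adjusted p = 0.0036), with 0.64 and 0.67 on the individual arrays. This is under the 2-fold minimum, so ORA47 was not called. Over uninduced, where both channels carry the transgene, it was 0.30 ± 0.07 (adjusted p = 0.067). With median centring in place of loess the ratio over WT was 1.24 and was called. Whether the probe lies in the part of ORA47 carried by the transgene is not given in the sources used here.

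Induced ORA47-GR seedlings differed from equally treated WT seedlings in 2167 of 24454 tested genes, 811 higher and 1356 lower, an excess of falls that reversed with median centring in place of loess (1222 higher and 835 lower). AT4G28140, an AP2-domain transcription factor, rose most, 29.3-fold (log2 4.87 ± 0.23, SE, n = 2; limma adjusted p = 0.0014). MRD1 (AT1G53480) rose 22.6-fold, the MATE-type efflux protein AT3G23550 20.5-fold, AT4G22620, annotated as auxin-responsive, 20-fold, and the AP2-domain factor ERF53 (AT2G20880) rose by 4.12 ± 0.17 on the log2 scale. Log2 rises between 3.47 and 3.85 were measured for AT14A, AT2G33830, AT4G33467, AT4G16000, AT1G17960, AT2G15960 and the cation/proton exchanger CHX17. The pathogenesis-related gene AT4G33720 fell most, 17.2-fold (log2 -4.10 ± 0.14, adjusted p = 0.0014). It was followed by the lipid transfer protein gene LTP4 (-3.58 ± 0.50), the xyloglucan-modifying XTH26 (-3.53 ± 0.20; 1 of its 2 probes went the other way), the beta-glucosidase BGLU32 (-3.44), GSTF14 (-3.35), AT1G77530 (-3.31), the arabinogalactan protein gene AGP30 (-3.30) and AIR1 (-3.25).

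The jasmonate biosynthesis list shifted up over WT by camera at the preset correlation. Of 21 measured members 7 rose and none fell by at least 2-fold, also 7 when adjusted over the list alone. The list median was 0.26 (camera adjusted p = 0.041, adjusted p = 0.87 with an estimated correlation), or 0.77 with median centring. Its members did not all move one way, with 14 above 0 and 7 below, and fry did not pass (adjusted p = 0.11). Among the 7, OPCL1 was at -0.94 (limma adjusted p = 0.0054) and LOX3 at -0.92 (limma adjusted p = 0.021). The lipase gene DGL rose by 3.24 ± 0.18 on the log2 scale, the allene oxide cyclase genes AOC2 and AOC1 by 2.17 ± 0.10 and 2.11 ± 0.27, and JAR1, which joins jasmonate to isoleucine, by 1.66 ± 0.15. The JAZ repressor list shifted down by camera at the preset correlation. Of its members 11 lay below 0 and 2 above, and fry did not pass (adjusted p = 0.24). Of 13 members 4 fell, 6 when adjusted over the list alone, with a median of -0.70 (adjusted p = 0.041; adjusted p = 0.87 with an estimated correlation), among them JAZ7 (-2.11 ± 0.40), JAZ13 (-1.97 ± 0.56), JAZ6 (-1.21 ± 0.32) and JAZ5 (-1.10 ± 0.17). Of 12 jasmonate and wound response outputs 3 fell, 4 when adjusted over the list alone, with a median of -0.84 (adjusted p = 0.041; adjusted p = 0.83 with an estimated correlation; 0.055 as the highest adjusted p under another scaling). These were the chitinase gene CHIB (-1.80 ± 0.10), ERF1 (-1.42 ± 0.24) and PR4 (-1.13 ± 0.21). MYC2 (-1.03 ± 0.17) and JAM1 (-1.05 ± 0.20) fell among 10 core signalling genes, 2 also when adjusted over the list alone. This list was not called by camera (median -0.18, adjusted p = 0.12), while by fry its genes moved down on balance (adjusted p = 0.031; 8 of 10 below 0). Among 10 catabolism genes JOX4 fell (-2.15 ± 0.62) and CYP94B3 rose (2.29-fold), neither when adjusted over the list alone (list adjusted p = 0.82).

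AP2/ERF transcription factor genes went both ways over WT. Of 24 members 9 fell and 2 rose, the same counts when adjusted over the list alone, with a median of -0.62 (camera adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation). The cold-response factor CBF2 (-2.95 ± 0.10), ERF109 (-2.94 ± 0.16), ERF017 (-2.85 ± 0.19) and DDF1 (-2.66 ± 0.30) fell most. With median centring, which moved the median of all genes over WT to 0.14, the list's median turned to 0.09 while camera still placed the list lower (adjusted p = 0.0092). Among 18 early touch, wound and elicitor genes 4 fell, including MYB15 (-1.71 ± 0.13), WRKY46 (-1.59 ± 0.13) and CAF1B (-1.27 ± 0.14), and ZAT6 rose (1.12 ± 0.10), with equal counts adjusted over the list alone and no list shift (median -0.13, adjusted p = 0.50). Salicylic acid defence genes were lower, with 3 of 12 down by either adjustment and a median of -0.72 (adjusted p = 0.033; adjusted p = 0.75 with an estimated correlation), or -0.19 with median centring (adjusted p = 0.049). NIMIN1 (-1.89 ± 0.10), the salicylate synthesis gene ICS1 (-1.48 ± 0.09) and PAD4 (-1.35 ± 0.11) fell.

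Cuticle and wax genes fell in 5 of 7 cases over WT, also when adjusted over the list alone. Their median was -1.05 (camera adjusted p = 0.036, adjusted p = 0.75 with an estimated correlation), or -0.53 with median centring. LTP4, LTP3 (-2.06 ± 0.31), the alkane-forming CER1 (-1.29 ± 0.17) and the regulator MYB96 (-1.05 ± 0.08) were among them. Of 7 cell cycle genes 1 fell by either adjustment, CYCB1;2 (-1.07 ± 0.13), and the list median was -0.85 (adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation). Of 13 heat shock genes none was called by either adjustment, while the list stood lower with a median of -0.43 (adjusted p = 0.041; adjusted p = 0.75 with an estimated correlation); HSP18.2 was at -0.72 and HSP21 at -0.69. Of 15 root markers 4 fell, 5 when adjusted over the list alone, and 1 rose, with a median of -0.56 (adjusted p = 0.064). The endodermal CASP1 (-1.24 ± 0.13) and the root-hair gene COBL9 (-1.12 ± 0.20) were among those that fell, and the iron transporter gene IRT1 rose (3.09 ± 0.31). None of 18 photosynthesis genes was called by either adjustment (median -0.01, adjusted p = 0.81), while with median centring the list was called higher (median 0.69, adjusted p = 0.0063), and LHCB3 was at -0.84 and LHCB2.2 at -0.79 with loess.

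Circadian clock genes split by their time of day over WT. Of 11 members 4 rose and 2 fell by either adjustment, with a list median of 0.80 (camera adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation). CCR2 (1.58 ± 0.14) and ELF4 (2.83-fold) rose, and the morning genes PRR9 (-1.65 ± 0.31) and CCA1 (-1.47 ± 0.40) fell. Of 13 genes often used as expression references UBQ10 (1.55 ± 0.10) and GAPC1 (1.51 ± 0.09) rose, 2 by either adjustment, with a median of 0.21 (adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation). With median centring the list medians were 1.16 for clock and 0.81 for reference genes, -0.43 for JAZ repressors, -0.57 for jasmonate and wound outputs, -0.33 for heat shock and -0.57 for cell cycle genes.

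Hormone and metabolic lists without a shift over WT still held called genes, and their counts adjusted over the list alone were the same. The abscisic acid receptor genes PYL5 (2.06 ± 0.14) and PYL9 (1.35 ± 0.08) rose among 22 abscisic acid signalling genes (list median -0.00, mean 0.07, camera adjusted p = 0.90). The catabolic CYP707A1 (-1.14 ± 0.18) fell among 13 abscisic acid synthesis and catabolism genes (median -0.48, adjusted p = 0.37). COR15A rose (2.57 ± 0.54) and GOLS3 fell (-1.19 ± 0.27) among 14 cold and drought genes (median 0.33, adjusted p = 0.48). GA2OX8 (1.90 ± 0.18) and GA2OX6 (1.45 ± 0.07), which inactivate gibberellin, rose and GA3OX1 (-1.20 ± 0.14) fell among 11 gibberellin genes (median -0.17 but mean 0.05, adjusted p = 0.79). ACO1 (-1.98 ± 0.15) and ACS6 (-1.03 ± 0.10) fell among 12 ethylene genes (median 0.11 but mean -0.10, adjusted p = 0.89). IAA6 (-2.82 ± 0.16) and IAA19 (-1.03 ± 0.15) fell and IAA2 (1.04 ± 0.17) rose among 11 auxin response genes (median -0.17, adjusted p = 0.46). GSTU4 (2.07 ± 0.20), UGT74E2 (2.03 ± 0.08) and GSTU5 (1.15 ± 0.16) rose and CYP81D11 (-1.99 ± 0.17) fell among 22 detoxification genes (median 0.13, adjusted p = 0.32). No gene was called among 12 glucosinolate, tryptophan and camalexin genes (median -0.04, adjusted p = 0.77; MYB34 at -0.91, CYP79B2 at -0.71) or 174 ribosomal protein genes (median 0.01, adjusted p = 0.79; AT5G39850 at 0.91, AT2G07725 at 0.80).

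Against uninduced seedlings of the same line, 427 genes changed, 348 higher and 79 lower, so 81.5% of the calls were rises. Over WT this share was 37.4%, or 59.4% with median centring. Over uninduced it was 84.1% with median centring (185 higher and 35 lower), 67.4% with the Feature Extraction log ratio (524 and 253) and 50.6% without a fold minimum (1085 and 1060). AT4G28140 again led (3.62 ± 0.23, SE, n = 2; limma adjusted p = 0.021), followed by BT3 (AT1G05690), a BTB and TAZ domain gene (3.09 ± 0.24). AT1G10140 (2.78), ERF53 (2.76), the protease inhibitor gene AT2G38870 (2.69), AT2G27320 (2.49), DIN11 (2.48), AT1G72060 (2.48), the fatty acid reductase gene FAR5 (2.47), AT4G04480 (2.45), the lipase gene GLIP1 (2.45) and the dehydrin gene AT4G38410 (2.41) completed the 12 largest rises. The falls were smaller. AT1G68360 (-1.87 ± 0.29), SAUR22 (-1.84 ± 0.09), AT1G30190 (-1.80), the aldolase gene FBA5 (-1.77), the nitrate transporter gene NRT1.5 (-1.72), AT3G50800 (-1.69), the light-harvesting gene LHCB2.3 (-1.67) and AT5G18030 (-1.65) led. The smallest adjusted p was 0.020, so no gene passed 0.01. Leaving out replicate 1 of this comparison left 0 limma calls (1770 up and 2429 down at an unadjusted p under 0.05), and leaving out replicate 2 also left 0 (2377 and 1888).

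Detoxification genes rose over uninduced in 8 of 22 cases and none fell, also when adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.4e-07; adjusted p = 0.56 with an estimated correlation). The glutathione transferase genes GSTU10 (1.62 ± 0.20) and GSTU11 (1.49 ± 0.12), CYP81D8 (1.53 ± 0.19) and UGT74E2 (1.48 ± 0.08) led. Of 21 jasmonate biosynthesis genes AOC1 (1.73 ± 0.27) and DGL (1.38 ± 0.18) rose, 3 when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.00020; adjusted p = 0.77 with an estimated correlation). Early touch, wound and elicitor genes shifted up with a median of 0.46 (adjusted p = 5.4e-05; adjusted p = 0.63 with an estimated correlation), though by either adjustment only 2 of 18 rose, ZAT6 (1.67 ± 0.10) and ZAT11 (1.03 ± 0.12), and 1 fell, WRKY46 (-1.24 ± 0.13).

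Auxin, green-tissue, root and cell cycle lists shifted down over uninduced. Of 11 auxin response genes IAA1 (-1.40 ± 0.10) and IAA5 (-1.17 ± 0.07) fell, 3 when adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.00032; adjusted p = 0.63 with an estimated correlation). Of 18 photosynthesis genes 1 fell by either adjustment, LHCB2.2 (-1.29 ± 0.07), with a median of -0.47 (adjusted p = 5.4e-05; adjusted p = 0.63 with an estimated correlation; 0.11 with median centring). No root marker and no cell cycle gene was called by either adjustment, with medians of -0.35 over 15 genes (adjusted p = 0.013; adjusted p = 0.63 with an estimated correlation) and -0.39 over 7 (adjusted p = 0.0020; adjusted p = 0.65 with an estimated correlation). IRT1 was at -0.73, SHR at -0.71, CYCB1;1 at -0.46 and CYCD3;1 at -0.42.

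Lists without a shift over uninduced held few called genes. ABR1 (1.57 ± 0.17) and DEAR1 (1.52 ± 0.18) rose and CBF2 (-1.10 ± 0.10) fell among 24 AP2/ERF genes, 3 and 2 when adjusted over the list alone (list median -0.13, camera adjusted p = 0.43). In the next 5 lists the counts were equal when adjusted over the list alone. PYL5 rose (1.14 ± 0.14) and the phosphatase gene ABI1 fell (-1.21 ± 0.11) among 22 abscisic acid signalling genes (median -0.06, adjusted p = 0.82). GOLS2 rose (1.48 ± 0.19) among 14 cold and drought genes (median -0.44, adjusted p = 0.44), ACS8 (1.48 ± 0.22) among 12 ethylene genes (median 0.05, adjusted p = 0.32) and GA2OX6 (1.43 ± 0.07) among 11 gibberellin genes (median -0.23 but mean 0.05, adjusted p = 0.44). ORA59 fell (-1.17 ± 0.13) among 12 jasmonate and wound outputs (median 0.25, adjusted p = 0.20).

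In 11 further lists over uninduced no member was called by either adjustment. JAZ repressors had a median of 0.32 (camera adjusted p = 0.12; JAZ8 at 1.32, JAZ10 at 1.04) and jasmonate catabolism genes one of 0.47 (adjusted p = 0.062; CYP94B1 at 1.40, JOX3 at 1.22). Core jasmonate signalling genes lay at -0.16 (adjusted p = 0.15; JAM1 at -0.74, JAM2 at 0.73) and abscisic acid synthesis and catabolism genes at -0.15 (adjusted p = 0.075; CYP707A3 at -0.98, AAO3 at 0.85). Heat shock genes lay at -0.01 with a mean of 0.06 (adjusted p = 0.96; HSP18.2 at 0.93, HSP70 at 0.39) and salicylic acid genes at 0.03 with a mean of -0.03 (adjusted p = 0.82; PR2 at 1.08, PAD4 at -0.79). Glucosinolate, tryptophan and camalexin genes lay at -0.22 (adjusted p = 0.99; PAD3 at 0.92, ASA1 at 0.66) and cuticle and wax genes at -0.27 (adjusted p = 0.20; CER6 at -0.51, KCS1 at -0.31). Reference genes lay at 0.14 (adjusted p = 0.072; GAPC1 at 0.60, UBQ10 at 0.45), clock genes at -0.05 (adjusted p = 0.96; GI at -0.26, CCR2 at -0.24) and ribosomal protein genes at 0.03 (adjusted p = 0.12; RPSAb at 0.55, AT3G49910 at 0.38).

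**Figure D1:**
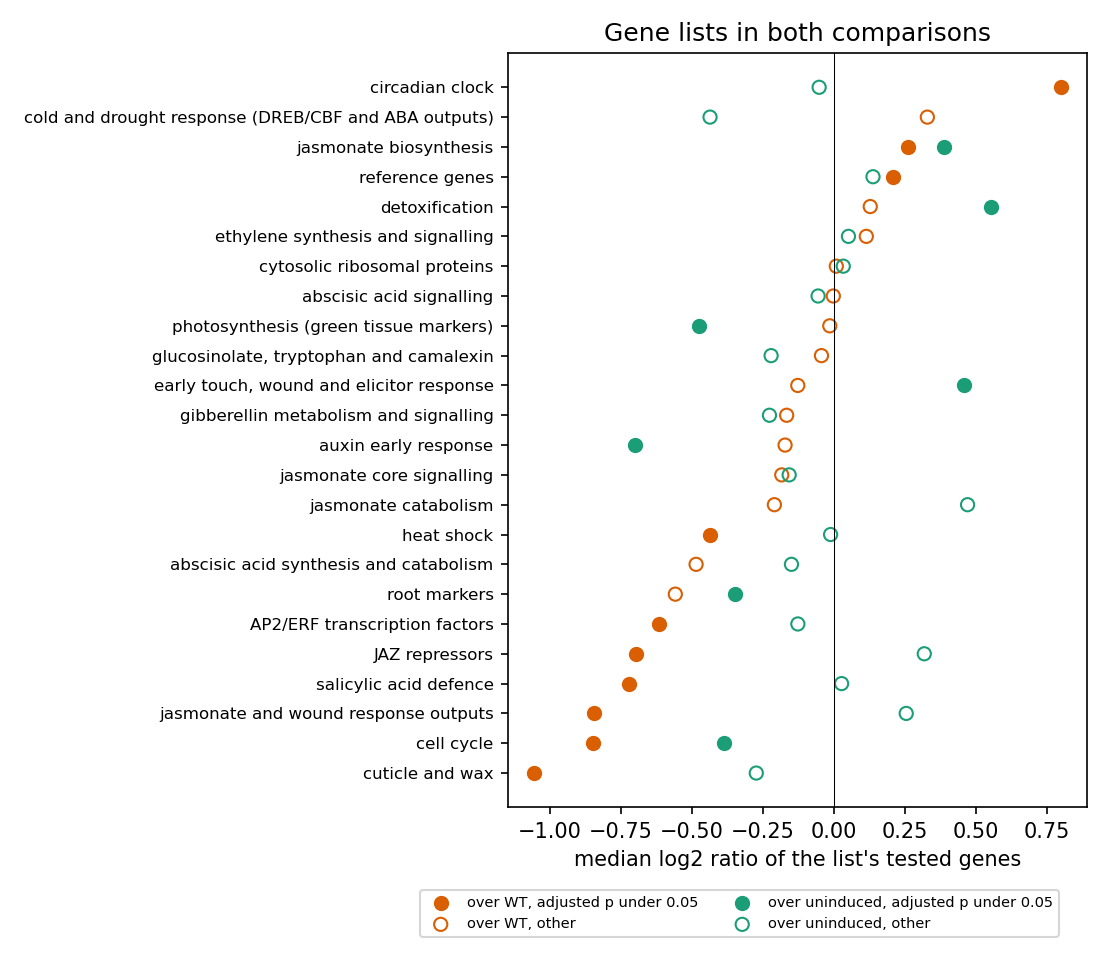
Median log2 ratio of each gene list's tested members (x axis) over WT (orange) and over uninduced (green), with filled points where the camera adjusted p was under 0.05 at the preset correlation. The detoxification list lies at 0.55 over uninduced and 0.13 over WT, and the JAZ repressor list at 0.32 and -0.70.

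The genes raised in both comparisons, which the study took as putative direct targets, numbered 125. With median centring 85 genes were up in both, 58 of them among these 125. Taking the median of all probes of a gene left 99 up in both, all among the 125. No gene was up in both by limma at an adjusted p under 0.01 or without either array over uninduced, where 1770 and 2377 genes were higher over uninduced at an unadjusted p under 0.05 (3341 with all arrays). If the lists were independent, 11.5 would be expected, and 35.9% of the rises over uninduced were also rises over WT. Of the 125, 11 stood at least 4.1-fold higher in both and 59 in at least one, the fold the study used for its 100 most raised genes. AT4G28140 was followed, by the smaller of its ratios, by BT3 (3.29 ± 0.24 over WT and 3.09 ± 0.24 over uninduced), ERF53 (4.12 and 2.76), DIN11 (3.05 and 2.48), AT4G22620 (4.32 and 2.37), the MYB factor gene MYB74 (2.75 and 2.36), the exostosin-family gene AT1G68470 (2.35 and 2.40), the phosphatase gene PP2C5 (2.12 and 2.23), AT1G53633 (6.07-fold and 4.23-fold) and AT2G32240 (2.73 and 2.08). Members of the fixed lists in this set included AOC1, DGL, ABR1, DEAR1, PYL5, GA2OX6, UGT74E2, GSTU4 and ZAT6.

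Genes lower in both numbered 42, against 4.38 expected. There were 14 with median centring (12 of them among the 42) and 121 with the Feature Extraction log ratio, and by limma 0 at an adjusted p under 0.01 or without either array over uninduced, where 2429 and 1888 genes were lower over uninduced at an unadjusted p under 0.05 (4009 with all arrays). The small auxin up RNA genes SAUR22 (-1.80 ± 0.09 over WT and -1.84 ± 0.09 over uninduced), SAUR23 (-1.63 and -1.64), SAUR24 (-1.53 and -1.59) and SAUR19 (-1.51 and -1.44) were among the 10 largest, as were AT4G13790 (-1.81 and -1.57), NRT1.5 (-1.57 and -1.72), AT1G30190 (-1.56 and -1.80), AT3G50800 (-1.52 and -1.69), the calcium-binding MSS3 (-1.65 and -1.51) and AT1G68360 (-1.41 and -1.87). SAUR19, SAUR22, SAUR23 and SAUR24 are close paralogs, and whether each probe reads one of them alone was not tested. Only 1 gene was called up over WT and down over uninduced, and 22 were called the reverse. Of the 348 rises over uninduced, 106 had a mean log2 ratio below 0 over WT, called or not.

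Both comparisons share the Cy5 condition. In 100 simulations of unchanged genes with a shared Cy5 RNA, at most 1 gene was up in both and none was down in both. Across genes the ratios correlated with r = 0.32, below the simulated 0.50, while their covariance was 0.068 against a simulated 0.0069. The simulations held noise alone, with no changed gene. They therefore cannot show how much of the observed overlap a shared Cy5 RNA gives. Part of the overlap may come from the shared condition or dye. With median centring r was 0.013.

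**Figure D2:**
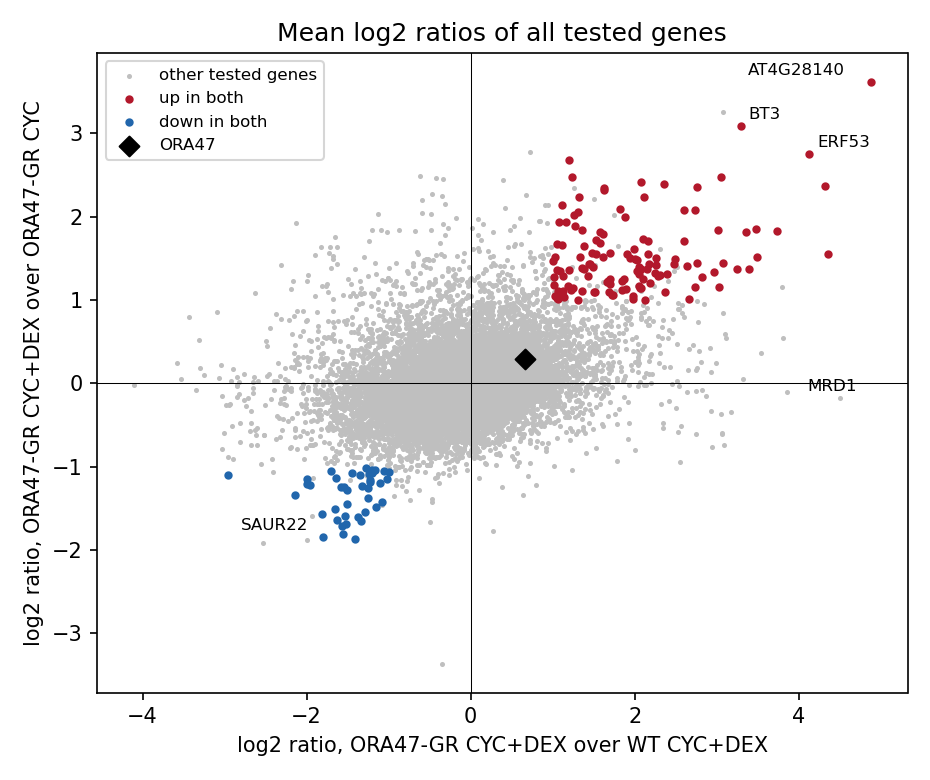
Mean log2 ratio of each tested gene over WT (x axis) and over uninduced (y axis), n = 2 arrays each. The 125 genes up in both (red) reach 4.87 and 3.62 at AT4G28140, the 42 down in both are blue, and ORA47 (diamond) lies at 0.66 and 0.30.

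**Figure D3:**
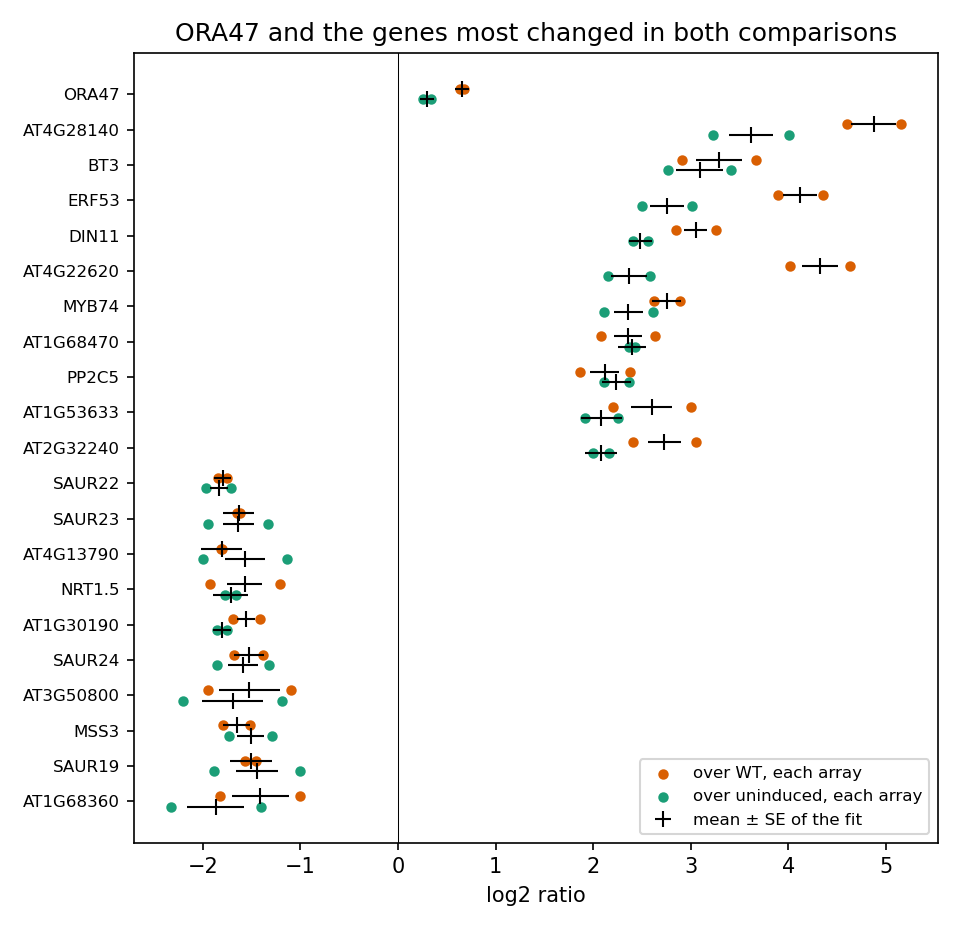
Log2 ratios of ORA47 and of the 10 genes most raised and the 10 most lowered in both comparisons, with each array as a point and the mean ± SE of the fit as a black bar. BT3 lies at 3.29 over WT and 3.09 over uninduced, and SAUR22 at -1.80 and -1.84.

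The comparisons themselves differed in 1770 genes, 565 with a higher and 1205 with a lower ratio over WT, and in 635 with median centring. Since the Cy5 condition is common, this contrast sets uninduced ORA47-GR against DEX-treated WT, and a gene-specific dye effect cancels in it. MRD1 (difference 4.68, limma adjusted p = 0.0082) and AT14A (3.95) led the higher ratios. The iron-uptake gene IRT1 (3.82), the iron-response factor gene BHLH100 (3.70) and ZIP8 (3.68) came next. BGLU32 (-4.23), AT4G33720 (-4.09), the AP2/ERF gene ESE1 (-4.05), AT1G77530 (-3.83) and LTP4 (-3.83) led the lower ones. Without replicate 1 over uninduced 0 such limma calls were left (3054 up and 3438 down at an unadjusted p under 0.05), and without replicate 2 also 0 (2790 and 4190).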

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

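The tests of replicate spread, root share, clock phase and probe base composition were all chosen after the results they address were seen.

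The ratios over WT and over uninduced differed in 1770 genes by a test of the difference itself, and in 635 with median centring in place of loess. With the Cy5 condition common to both, it sets uninduced ORA47-GR against DEX-treated WT, so line and DEX change together. The 5 largest positive differences were those of MRD1 (4.68), AT14A (3.95), the iron-uptake gene IRT1, the iron-response factor gene BHLH100 (3.70) and ZIP8 (3.68). For IRT1 the difference was 3.82, with 3.09 over WT and -0.73 over uninduced. No list of iron genes was tested. BGLU32 (-4.23), AT4G33720 (-4.09), ESE1 (-4.05; -2.12 over WT and 1.92 over uninduced), AT1G77530 (-3.83) and LTP4 (-3.83) were the 5 largest negative ones.

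Among the gene lists 10 differed between the comparisons with camera at its preset correlation, and none with an estimated correlation (adjusted p from 0.754 to 0.784). Ratios were lower over WT than over uninduced for JAZ repressors (median difference -0.93, camera adjusted p = 0.0092), jasmonate and wound outputs (-0.92, 0.021) and cuticle and wax genes (-0.91, 0.037). The same held for early touch genes (-0.57, 0.00034), salicylic acid genes (-0.52, 0.014) and AP2/ERF genes (-0.46, 0.014). Detoxification genes (-0.44, 0.035) and heat shock genes (-0.30, 0.036) also had lower ratios over WT than over uninduced. Clock genes (0.71, camera adjusted p = 0.021) and photosynthesis genes (0.30, 0.0011) had higher ones. A difference need not mean a shift over WT. Detoxification medians were 0.13 over WT and 0.55 over uninduced, and photosynthesis medians were -0.01 and -0.47. With median centring the medians were -0.46 for JAZ repressors, -0.79 for jasmonate and wound outputs, -0.38 for cuticle and wax, -0.09 for early touch, -0.18 for salicylic acid, -0.44 for heat shock, 1.17 for clock and 0.73 for photosynthesis genes. There the AP2/ERF and detoxification medians turned to 0.04 and 0.05, and early touch, detoxification and salicylic acid genes lost their calls (adjusted p = 0.24, 0.90 and 0.23). Cuticle and wax genes lost theirs without background subtraction, with the Feature Extraction log ratio and with the deposited values (adjusted p = 0.059, 0.052 and 0.052), and with a replicate block (0.054).

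The size of the response over WT, 2167 genes against 427, was weighed against technical causes. A larger spread between the over-WT replicates is argued against by a spread only 1.14 times that over uninduced, while the mean ratios spread 1.70 times as widely. A smaller share of root tissue was not excluded. The root markers did not fall alike, since their log2 ratios over WT had an SD of 1.15 against a median SE of 0.13. The rise of IRT1 widens that SD, and 12 of the 15 markers lay below 0 and 3 above (median -0.56). Markers need not fall by equal amounts when the root share drops, so this test cannot decide. Another clock phase in the WT seedlings may contribute, since the evening genes lay 2.49 above the morning genes in the difference between comparisons (medians 1.00 for 7 and -1.49 for 3) but 0.02 over uninduced. The split left out PRR7, a day gene, whose difference of 0.52 went with the evening genes. The difference in line and in DEX treatment stays open and was not tested.

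The 125 genes that rose in both comparisons were weighed against dye effects, since no dye swap was made. An effect of probe base composition is argued against by the 50 other tested probes nearest in composition to each gene. Their median log2 ratio was -0.0064 as a median over the 125 genes and at most 0.12 for any of them, against an observed 1.68. Other gene-specific dye effects, alone or added to a difference of line or DEX, could give these ratios and stay open; 23 of the 125 differed between the comparisons, 22 of them with the larger ratio over WT. Direct activation by ORA47, the design's own explanation, is a hypothesis that these arrays leave open.

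Probes that matched no locus lie outside the comparisons by gene. Of 4578 tested together with the genes, 4 rose in both comparisons, with 114 up and 78 down over WT and 16 up and 2 down over uninduced. Of 153 negative-control spots 4 were well above background on any array.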

How the results depend on the processing

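Every alternative was planned except the crossed replicate block. The cause of a change was not tested unless stated.

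Median centring in place of loess gave 1222 genes up and 835 down over WT, 185 up and 35 down over uninduced, 14 down in both and 635 differing between comparisons, so that rises outnumbered falls over WT, the reverse of the main result. It raised ORA47 over WT to 1.24 and brought the correlation of the comparisons to 0.013. It reversed the medians of photosynthesis genes over WT (0.69, adjusted p = 0.0063) and of ribosomal genes between comparisons (0.43, adjusted p = 0.0070). Without background subtraction 127 genes were down over uninduced. The Feature Extraction log ratio gave 524 up and 253 down over uninduced and 121 down in both, and the deposited values gave 250 genes down over uninduced and 120 down in both.

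Without a fold minimum 4749 and 5984 genes were up and down over WT, 1085 and 1060 over uninduced, 542 and 619 in both, and 5184 differed, since fewer conditions apply. Testing against 1.5-fold left 0 limma calls over uninduced and 0 in both (557 up and 204 down over uninduced at an unadjusted p under 0.05) and 337 differing. An adjusted p under 0.01 left 0 over uninduced and 0 in both (3341 and 4009 unadjusted) and 250 differing. A 2-fold change on every array, without a p, gave 47 down over uninduced, 22 down in both and 1077 differing.

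Leaving out single arrays, where the lone array is assumed to vary like the others, gave 668 to 949 genes up and 1233 to 1447 down over WT, 0 to 351 up and 0 to 77 down over uninduced, 0 to 148 up and 0 to 44 down in both, and 0 to 1719 differing. The limma counts of 0 came without either over-uninduced array (1770 up and 2429 down unadjusted without replicate 1, 2377 and 1888 without replicate 2), where fewer arrays remain. Ribosomal medians ranged from -0.16 to 0.16 over WT and from -0.19 to 0.11 between comparisons.

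A replicate block by equal numbers gave 792 genes up and 1332 down over WT, 292 and 71 over uninduced, and 93 and 39 in both. Pairing the replicates crosswise, chosen after seeing the data, gave 819 and 1382, 426 and 85, and 147 and 45. Quantile normalization of the mean signals leaves the ratios unchanged by construction.

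Of 1056 values of gene lists 997 kept their side of the threshold and, where called, the direction given by camera, 23 became weaker, 32 stronger and 4 reversed. With median centring 3 further medians changed sign while camera's direction did not, those of AP2/ERF genes over WT (0.09) and between comparisons (0.04) and of detoxification genes between comparisons (0.05). Of 4214 values of named genes 3745 did so, 440 became weaker, 29 stronger and none reversed. Many of these values could not reverse. Alternatives of the model, the thresholds, the filter and quantile normalization leave a gene's ratio as it is. So does leaving out an array of the other comparison. The deposited values nearly repeat the Feature Extraction log ratio. These counts are therefore not a measure of robustness by themselves. The number of arrays limits the precision. The 6 alternatives for promoter motif enrichment were not run, since no genome was used.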

Other observations

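The tests of ORA47 and of neighbouring genes were chosen after their results were seen, as were the families described.

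Genes grouped by the stem of their symbol, with at least 8 tested members, gave 237 families. Genes known only by a locus tag joined no family, so a family here can be a part of the whole. The 16 genes with a SAUR symbol had medians below 0 in both comparisons. They include the close paralogs SAUR19, SAUR22, SAUR23 and SAUR24. Whether each probe reads its own gene alone was not tested, so counts of SAUR genes may repeat some transcripts. Over WT the median was -1.04, and 8 fell and 1 rose (camera adjusted p = 0.014, adjusted p = 0.989 with an estimated correlation). Over uninduced it was -0.65, and 7 fell and 1 rose (camera adjusted p = 0.00076, adjusted p = 0.994 with an estimated correlation). Under 4 other scalings these medians ranged from -1.45 to -1.08 over WT and from -1.70 (Feature Extraction log ratio) to -0.47 (median centring) over uninduced. The medians of the 33 TRM genes lay below 0 in both as well, at -0.34 and -0.32, though only 5 genes fell over WT and none over uninduced. The camera adjusted p was 0.014 and 0.00042, and 0.989 and 0.994 with an estimated correlation. The 9 LHCB light-harvesting genes lay at -0.85 over uninduced, where 2 fell (adjusted p = 2.7e-05; adjusted p = 0.994 with an estimated correlation). In all, 8 families passed camera over WT and 8 over uninduced, and none with an estimated correlation.

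The ORA47 ratio over WT of 0.66 was weighed against technical causes. Scanner saturation is argued against by the ORA47 spot reaching at most 23.1% of the brightest Cy5 spot of its array. A sample of these ORA47-GR seedlings in place of WT is argued against by the overall distances. The smallest log2 distance of a WT channel from an ORA47-GR channel was 0.511, against at most 0.445 between any 2 ORA47-GR channels, across dyes and treatments. In the Cy3 channel of the treated WT seedlings the same probe read 22061 and 21736. The median gene spot read 664.1 and 585.5 in Cy3 on these arrays. After normalization its Cy3 level lay above 96.2% and 96.8% of the tested genes, so treated WT itself gave a clear ORA47 signal. Whether endogenous transcript keeps the ratio small was not tested, and signals of different probes are only roughly comparable in level.

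Neighbouring genes rose together in both comparisons in 7 pairs. Random gene sets matched on signal held 0.668 pairs on average and 5 at most, which argues against chance placement. The one-sided permutation p over these sets was 1e-04, the smallest that 10000 sets can give. The pairs were GA2OX6 and AT1G02405, UGT74E2 and BT3, AT1G53633 and AT1G53635, AT2G31940 and AT2G31945, AT4G16000 and AT4G16008, AT4G28140 and AT4G28150, and AT5G54165 and AT5G54170. Shared regulation, transcripts running into the next gene and probes reading both genes remain open and were not tested.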
